A study of Mus musculus with 6 samples.

How the data were processed

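Expression was measured on an Affymetrix mouse array in 6 samples of mesenchymal stem cells, 3 irradiated with pulsed terahertz radiation for 12 h and 3 controls. Labelled RNA was made from 200 ng of total RNA, per the labels' protocols. The deposited values are log2 expression per probe set, given to 2 decimals. They were made with RMA and the affy package, and limma is named beside these, per the submitters' processing notes. The background step, the set of arrays normalized together and the versions are not given in the sources used here. No genome build is named there either, so no coordinates are printed.

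The table has 45101 probe sets. The 64 array controls were left out of the tests, which leaves 45037. By the platform annotation given with the table, 34945 of these carry 1 gene symbol, 932 carry several and 9160 are unnamed here. Symbols of 34741 probe sets were matched through gene identifiers to the annotation of assembly GRCm38.p6. A gene was represented by the probe set with the highest mean over the 6 arrays, which gave 18193 genes, and probe sets with several symbols were not named. A gene was called expressed at a mean log2 value of at least 6 in 1 group, which held for 9302 genes. Rbm3 and Gapdh, which the rule for named genes asked for, had no probe set with that symbol alone in this annotation and are not analysed here.

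Irradiated and control arrays were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the deposited values, two-sided, with the experiment as a block and Benjamini-Hochberg adjustment over all probe sets at 0.05. The block was used because the design text states that in each independent experiment the irradiated culture was compared with its own adjacent control. The values bear this pairing out in part. Deviations from the group means correlated across genes at 0.787 for the pair of experiment 1, 0.028 for experiment 2 and 0.324 for experiment 3, and irradiated array 2 correlated best with control array 3, at 0.552. The pairing therefore rests on the design text. The fit had 2 residual degrees of freedom and a prior of 4.52. Log2 differences are irradiated minus control and their SE comes from this fit. Arrays correlated between 0.9889 and 0.9959 and no pair held the same values.

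Lists of genes were fixed before the data were examined. They covered fat, bone, cartilage, muscle and stromal cells, markers of other cell types, stress responses, signalling, metabolism and housekeeping processes, 33 lists in all. Of 784 distinct members 712 were measured, 5 of them under an older or newer symbol. Each list was tested with camera at an inter-gene correlation of 0.01, with adjustment over the 33 lists, and again with an estimated correlation and with fry. None of the 33 lists passed with either of the last 2. With an estimated correlation camera uses the residual degrees of freedom of the fit, 2 here and fewer with an experiment left out. So few leave almost no room to pass over 33 lists, and a large adjusted p there decides nothing. The estimated correlation was below 0.01 for the interferon list (0.000435) and the NF-kB list (-0.0284), so correlation did not end those calls. Members are also counted with p adjusted over the list alone, which does not correct for the number of lists.

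Genes were named by a rule fixed before the data were examined. Since fewer than 20 genes passed, it took up to 12 genes in each direction, expressed, at least 1.5-fold different and with 1 sign in all 3 experiments, in order of the moderated statistic. Clone names, gene models and accession-like symbols were skipped. From each list it took up to 4 expressed members with the largest statistic, and it fixed a set of fat cell, heat, cold, stress and housekeeping genes. Genes outside the rule are said to be so.

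The fit was tested on simulated pairs with 45037 probe sets and variances drawn from the fitted prior. At an adjusted p under 0.05, 78 of 100 probe sets changed 2-fold and 100 of 100 changed 4-fold were found, with 7 false calls. The simulated genes were independent of each other, so this says nothing about false calls of lists whose genes move together. The rates found hold only where as many probe sets change, since the adjusted threshold is stricter where fewer do. Gem, 4.68-fold lower in the deposited data, had a limma adjusted p of 0.224, so a 4-fold change could be missed. Alternatives were no block, a random block, each experiment left out, dim probe sets left out, quantile normalization, median centring, an intensity trend with a robust prior, array weights, 1 probe set per gene, ordinary paired statistics, and other filters and list tests. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.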

Results

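Genome-wide expression was measured in mouse mesenchymal stem cells, stromal cells that can turn into fat, bone or cartilage cells, kept in a medium that drives fat cell formation. The medium held rosiglitazone at 1 µM, insulin at 5 µg/ml, the phosphodiesterase inhibitor IBMX at 100 µM and the glucocorticoid dexamethasone at 1 µM. One group of cultures was exposed for 12 h to pulsed broadband terahertz radiation, which lies between microwaves and infrared light, centred near 10 THz. The pulses came at 1 kHz with an average power density of 1 mW/cm2. The control cultures stood beside the irradiated ones, and both were held at 26 to 27 °C. Each of the 3 independent experiments gave 1 irradiated and 1 control array, so there were 6 arrays and 3 pairs. All values are log2 expression per probe set as deposited, and the number of arrays limits the precision. Array medians lay between 4.74 and 4.80.

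The comparison asks which transcripts differ between irradiated cells and their own adjacent controls. By camera at the fixed correlation, heat shock genes fell and interferon response genes rose as groups, with list medians of -0.145 and 0.127. Camera adjusted p was 0.0014 for each, or 0.851 with an estimated correlation. Neither list passed with fry (fry adjusted p = 0.192 and 0.257). The interferon call was also lost without experiment 3 (camera adjusted p = 0.0979). The widest differences among the leading genes were lower values in irradiated cells. Gem, which encodes a small GTP-binding protein, had a mean of 8.28 ± 0.20 (SD, n = 3) in controls and 6.05 ± 0.34 (SD, n = 3) in irradiated cultures, 4.68-fold lower. Ifitm6, a member of the interferon-induced transmembrane family, was 2.79-fold lower, with a dim mean of 5.57 in irradiated cultures. Hspa4l, a chaperone of the Hsp110 family, was 2.04-fold lower. Fat cell genes gave no call as a list, and their medians of 0.14, -0.06 and -0.31 in the 3 experiments differed in sign.

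No probe set or gene passed Benjamini-Hochberg adjustment in the limma fit with the experiment as a block, and the smallest adjusted p was 0.188. At an unadjusted p under 0.05 there were 3631 of 45037 probe sets, 1739 higher and 1892 lower, where chance gives 2252. Without the replicate block the count was 2168, below that value, so the excess depends on the block. With the experiment as a random block 2 genes passed, Gem (adjusted p = 0.0262) and Rhpn2 (adjusted p = 0.0343). Rhpn2, named here after its values were seen, was dim in both groups, with means of 4.78 in controls and 3.47 in irradiated cells. An ordinary paired statistic without moderation called 15 probe sets, and each of these 15 had 3 differences that were equal to 2 decimals.

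Of 9302 expressed genes, 68 differed by at least 1.5-fold at an unadjusted p under 0.05, 19 higher and 49 lower in irradiated cells. All 68 differed in 1 direction in all 3 experiments, which these cut-offs favour. The count was 141 without experiment 2. The 12 leading genes in each direction are given as values, since none passed the adjusted threshold. Among those lower in irradiated cells, Crem, a transcription factor gene induced by cAMP, had a log2 difference of -0.83 ± 0.10 (SE). Of the 3 other Crem probe sets, the 1 above the level of 6 differed by -0.78 ± 0.09 (SE). Slc16a10, an aromatic amino acid transporter, differed by -0.92 ± 0.11 (SE). The neutrophil chemokine Cxcl1 differed by -0.76, the lipid phosphatase gene Inppl1 by -0.72 and Snapc1, a subunit of the complex that activates small nuclear RNA genes, by -0.70. Slc45a3, Sh3bgrl2, Mettl8 and Dubr lay between -0.83 and -0.65.

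Among the genes higher in irradiated cells, Rspo2, a secreted enhancer of Wnt signalling, had a log2 difference of 0.81 ± 0.10 (SE), and its other probe set was dim, at 5.25 in controls, and differed the other way, by -0.11 ± 0.12 (SE). Smad1, which carries bone morphogenetic protein signals, was higher by 0.67 with all 3 of its probe sets higher. The transcription factor gene Osr1 was higher by 0.73, the cytokine Il6 by 0.71, the pentraxin Ptx3 by 0.66 and the neurotrophic factor Gdnf by 0.63. Apol8, Cwf19l2, Zfp608, Mbip, Rbm43 and Smim3 lay between 0.59 and 0.90. Rbm43 differed by 0.28, 0.39 and 1.15 in the 3 experiments, and by 0.34 without experiment 3. Adjusted p values from limma ran from 0.224 for Gem to 0.551 for Rbm43 over the 24 leading genes.

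**Figure D1:**
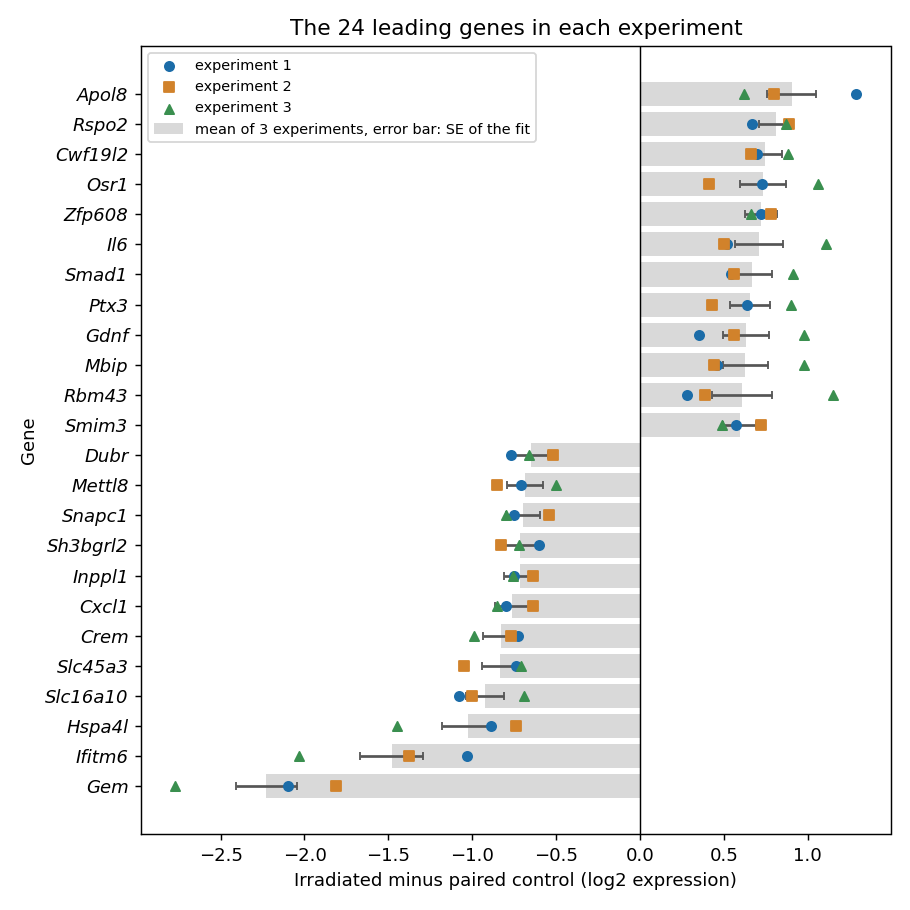
Log2 expression of irradiated minus paired control cultures (horizontal axis) for the 24 leading genes (vertical axis), with grey bars for the mean of 3 experiments, error bars for the standard error of the fit and points for single experiments. Every point lies on its bar's side of 0, as the rule that chose the genes requires, and Gem reaches from -1.81 to -2.77.

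The heat shock genes, which encode inducible chaperones and their partners, fell as a group in irradiated cells (camera adjusted p = 0.0014; adjusted p = 0.851 with an estimated correlation). Of 22 measured members 15 were lower, 11 of them in all 3 experiments, and 7 were higher. The inducible Hsp70 genes differed by the most, with log2 differences of -1.47 ± 0.28 (SE) for Hspa1a and -1.33 ± 0.26 (SE) for Hspa1b. Hspa1a differed by -1.30, -0.74 and -2.38 in the 3 experiments. Chordc1, which binds Hsp90, differed by -0.40 ± 0.11 (SE). Adjusted over the list alone 5 members passed, those 3, Hspa4l and Hsph1, against 0 over all genes tested. Hsph1, named after its values were seen, differed by -0.35 ± 0.09 (SE). The constitutive Hspa8 differed by 0.02 (95% interval -0.20 to 0.25) and Hspb1 by -0.16. List medians were -0.07, -0.19 and -0.12 in the 3 experiments. Without Hspa1a, Hspa1b and Hspa4l, an alternative chosen after seeing the data, the camera call was lost, with an adjusted p of 0.0631 and a median of -0.13. The full list did not pass with fry (fry adjusted p = 0.192).

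**Figure D2:**
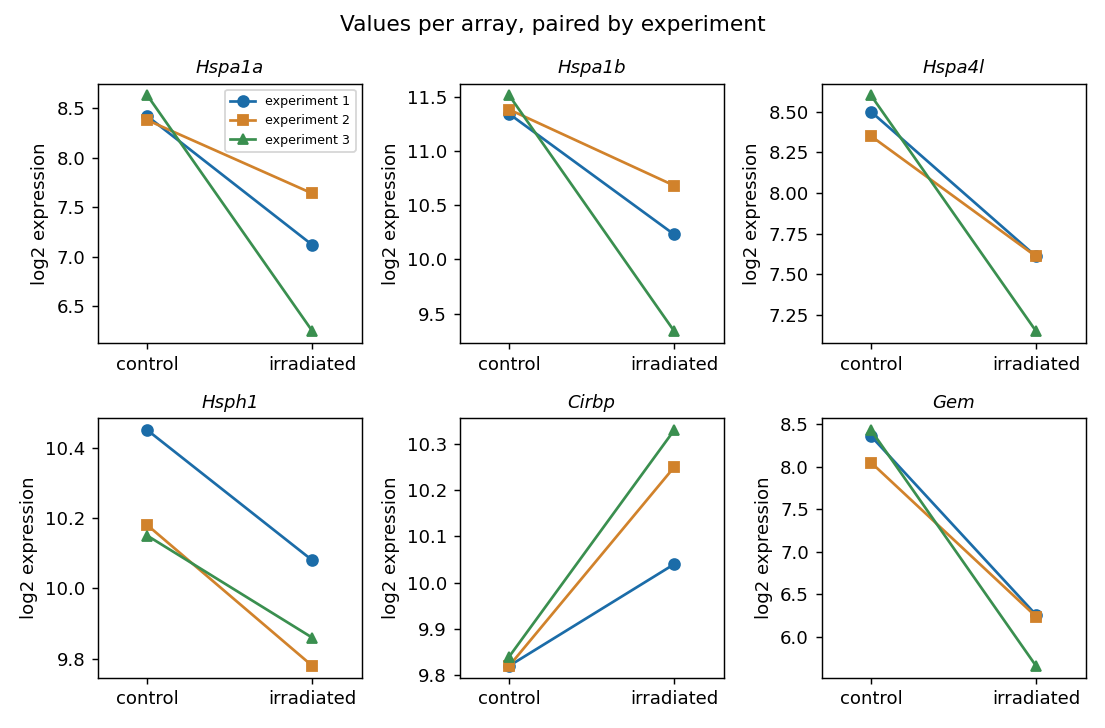
Log2 expression on each array (vertical axes) of 5 heat or cold response genes and Gem in control and irradiated cultures, with a line joining the 2 arrays of each experiment. Hspa1a, Hspa1b, Hspa4l, Hsph1 and Gem are lower in irradiated cells in all 3 experiments, and Cirbp is higher, by 0.22, 0.43 and 0.49.

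Other stress lists did not pass. The cold-inducible RNA-binding protein gene Cirbp had a log2 difference of 0.38 ± 0.10 (SE) and the splicing factor gene Srsf5 of 0.30 ± 0.09 (SE). In the cold response list of 5 measured genes, 4 passed when adjusted over the list alone, against 0 over all genes tested. They were Cirbp and Srsf5, which were higher, and Ucp1 and Ppargc1a, which were lower, dim and named after their values were seen. The list as a whole had a camera adjusted p of 0.799. Among oxidative stress genes, Slc7a11, the cystine transporter, differed by -0.54 ± 0.10 (SE). It was the single member past adjustment over the list alone, against 0 over all genes tested, while Hmox1 differed by 0.00, -0.38 and 0.48 in the 3 experiments. The list's median was -0.03 over 20 genes. The p53 and DNA damage list had a median of 0.08 over 25 genes, with Fas at 0.45 and Cdkn1a at -0.04 (95% interval -0.28 to 0.19), and camera adjusted p was 0.148. It rose without experiment 2 (adjusted p = 0.0226, or adjusted p = 0.924 with an estimated correlation). The unfolded protein response list had a median of -0.01 over 29 genes and fell without experiment 3 (adjusted p = 0.0355, or adjusted p = 0.907 with an estimated correlation). The apoptosis list had a median of 0.07 and a camera adjusted p of 0.148.

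Interferon response genes rose as a group (camera adjusted p = 0.0014; adjusted p = 0.851 with an estimated correlation). Of 27 measured members 23 were higher and 4 lower, 9 of them higher in all 3 experiments, but 10 were expressed above the level of 6. Psmb9, an immunoproteasome subunit, differed by 0.55 ± 0.09 (SE) and Tap1, a peptide transporter for antigen presentation, by 0.58 ± 0.10 (SE). These 2 passed adjustment over the list alone, against 0 over all genes tested. Tap1 was dim in controls, at 5.72, and its 3 other probe sets, at 2.37, 4.58 and 2.77 there, are too dim to bear on it. Gbp2 was higher by 0.19 and Ddx58 by 0.17. List medians were -0.02, 0.15 and 0.20 in the 3 experiments. The call was lost without experiment 3 (camera adjusted p = 0.0979), whose irradiated array had brighter hybridisation controls, described below.

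Genes of inflammation and NF-kB signalling fell as a group (camera adjusted p = 0.0236; adjusted p = 0.851 with an estimated correlation), with 20 of 31 measured members lower and 11 higher and medians of -0.17, -0.09 and -0.20 in the 3 experiments. Adjusted over the list alone 9 members passed, against 0 over all genes tested, and they went both ways. The neutrophil chemokine genes Cxcl1 and Cxcl5 differed by -0.76 and -0.58 ± 0.12 (SE), and Ptgs2, the inducible cyclooxygenase, by -0.56 ± 0.13 (SE). The cytokine Il6 differed by 0.71 and the adhesion molecule Vcam1 by 0.49 ± 0.13 (SE). Myeloid markers fell in the same comparison, with 17 of 20 lower, and lost their call under the same omissions of the replicate block and of experiment 1. The NF-kB call was lost without the replicate block (adjusted p = 0.161), without experiment 1 (adjusted p = 0.0924) and with dim probe sets left out (adjusted p = 0.153).

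Macrophage and myeloid markers fell as a group (camera adjusted p = 0.0236; adjusted p = 0.851 with an estimated correlation), with 17 of 20 measured members lower. Cd14, a receptor for bacterial lipopolysaccharide, differed by -0.73 ± 0.19 (SE) and Laptm5 by -0.19. List medians were -0.22, 0.07 and -0.12 in the 3 experiments. The call was lost without the replicate block (adjusted p = 0.28), with it as a random effect (adjusted p = 0.247), without experiment 1 (adjusted p = 0.414) and without experiment 3 (adjusted p = 0.166). Of the 20 markers 19 had a mean above the level of 6. Endothelial, lymphoid and erythroid, epithelial, and neural and glial markers had median log2 differences of -0.04, 0.07, 0.10 and 0.03, and none of these 4 lists passed. They lay mostly near background, with 1 of 15, 0 of 11, 2 of 13 and 1 of 12 measured members at a mean of at least 6. Their differences therefore say little about such cells.

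Genes of fat cell differentiation and lipid storage gave no call (camera adjusted p = 0.148). Of 35 measured members 26 were lower and 9 higher, and the list medians of 0.14, -0.06 and -0.31 differed in sign between the experiments. The master regulator Pparg differed by 0.34, 0.03 and -0.47 in the 3 experiments. Its mean of -0.03 (95% interval -0.42 to 0.35) became -0.22 without experiment 1 and 0.19 without experiment 3. Over the experiments Cebpa differed by 0.19, 0.15 and -0.15, the hormone gene Adipoq by 0.22, 0.03 and 0.01 and the lipase gene Lpl by 0.09, 0.01 and -0.12. The fatty acid carrier Fabp4 read 14.32 in controls and 14.30 in irradiated cells, close to the highest values on the arrays, 14.41 to 14.53, so a difference could be hidden there. Its other 3 probe sets differed by 0.30 ± 0.22 (SE), 0.06 ± 0.22 (SE) and -0.03 ± 0.10 (SE). The members with the largest statistics went both ways, Cebpd at 0.55 ± 0.14 (SE), Ebf1 at 0.49 ± 0.11 (SE) and the fatty acid synthase gene Fasn at -0.32 ± 0.11 (SE), and none passed, over the list alone either. Slc2a4, the insulin-responsive glucose transporter, differed by -0.22. Without experiment 1 this list fell (adjusted p = 0.000135, or adjusted p = 0.896 with an estimated correlation).

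Markers of the other mesenchymal fates did not pass. Osteoblast genes had a median log2 difference of -0.02 and chondrocyte genes of 0.05, with Col11a1 at 0.27. Smooth muscle and myofibroblast genes had a median of -0.07 with 11 of 14 lower, among them Actg2 at -0.37, and fell without experiment 3 (adjusted p = 0.0432, or adjusted p = 0.907 with an estimated correlation). Stromal cell markers had a median of 0.07, with Alcam at -0.33 and Pdgfrb at -0.28 opposite to Vcam1. Genes of collagens and the extracellular matrix rose as a group (camera adjusted p = 0.027; adjusted p = 0.851 with an estimated correlation), with 29 of 36 measured members higher and 13 of them higher in all 3 experiments. Myeloid markers fell in the same comparison, with 17 of 20 lower, and their call was lost under the same omissions of the replicate block and of experiment 1. The matrix median was 0.07, with the collagen lysyl hydroxylase Plod2 at 0.37 ± 0.10 (SE) and Vcan at 0.27. The call was lost without the replicate block (adjusted p = 0.167), with it as a random effect (adjusted p = 0.209) and without experiment 1 (adjusted p = 0.396).

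Cell cycle genes fell as a group (camera adjusted p = 0.0388; adjusted p = 0.851 with an estimated correlation), with 27 of 41 measured members lower. Prc1, a microtubule bundler of dividing cells, differed by -0.42 ± 0.12 (SE) and E2f1 by -0.29, while Uhrf1 was higher by 0.36. List medians were -0.08, 0.07 and -0.26 in the 3 experiments, and those of the myeloid markers, which also fell, were -0.22, 0.07 and -0.12. The call held under 3 of 17 alternatives and was lost without the replicate block (adjusted p = 0.0904), without experiment 1 (adjusted p = 0.34) and without experiment 3 (adjusted p = 0.401).

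The remaining lists gave no call. Cholesterol synthesis genes had a median log2 difference of -0.12 with 16 of 20 lower, including Srebf2 at -0.23, and fell without experiment 2 (adjusted p = 0.0226, or adjusted p = 0.924 with an estimated correlation). Fatty acid oxidation genes had a median of -0.02, with Cpt1a at -0.34 and Acot2 at 0.48, or 0.24 without experiment 3. Hypoxia and glycolysis genes had a median of -0.01, mitochondrial respiratory chain genes 0.01, ribosomal protein genes -0.01 and splicing factor genes 0.05. Among clock genes, whose median was -0.08, Per2 was lower at -0.43 ± 0.09 (SE) while Nr1d1 and Nr1d2 were higher by 0.31 and 0.34. The medians were 0.09 for immediate early genes, 0.09 for TGF-beta and BMP targets and 0.05 for Wnt genes, which rose with dim probe sets left out (adjusted p = 0.0251, or adjusted p = 0.813 with an estimated correlation). Past adjustment over the list alone were Ier3 at -0.75 and Fosl2 at 0.42 among immediate early genes, Id4 at 0.50 among TGF-beta and BMP targets and Crem in the cAMP list. None of these passed over all genes tested. Actin and YAP targets had a median of 0.05 and rose without experiment 2 (adjusted p = 0.0262, or adjusted p = 0.924 with an estimated correlation). In that list Ccn2, a matricellular growth factor, differed by 0.64, 0.35 and 2.19 in the 3 experiments, a mean of 1.06 that was 0.50 without experiment 3. Glucocorticoid targets had a median of -0.01 and cAMP targets of 0.06, and in both the test pointed the other way.

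**Figure D3:**
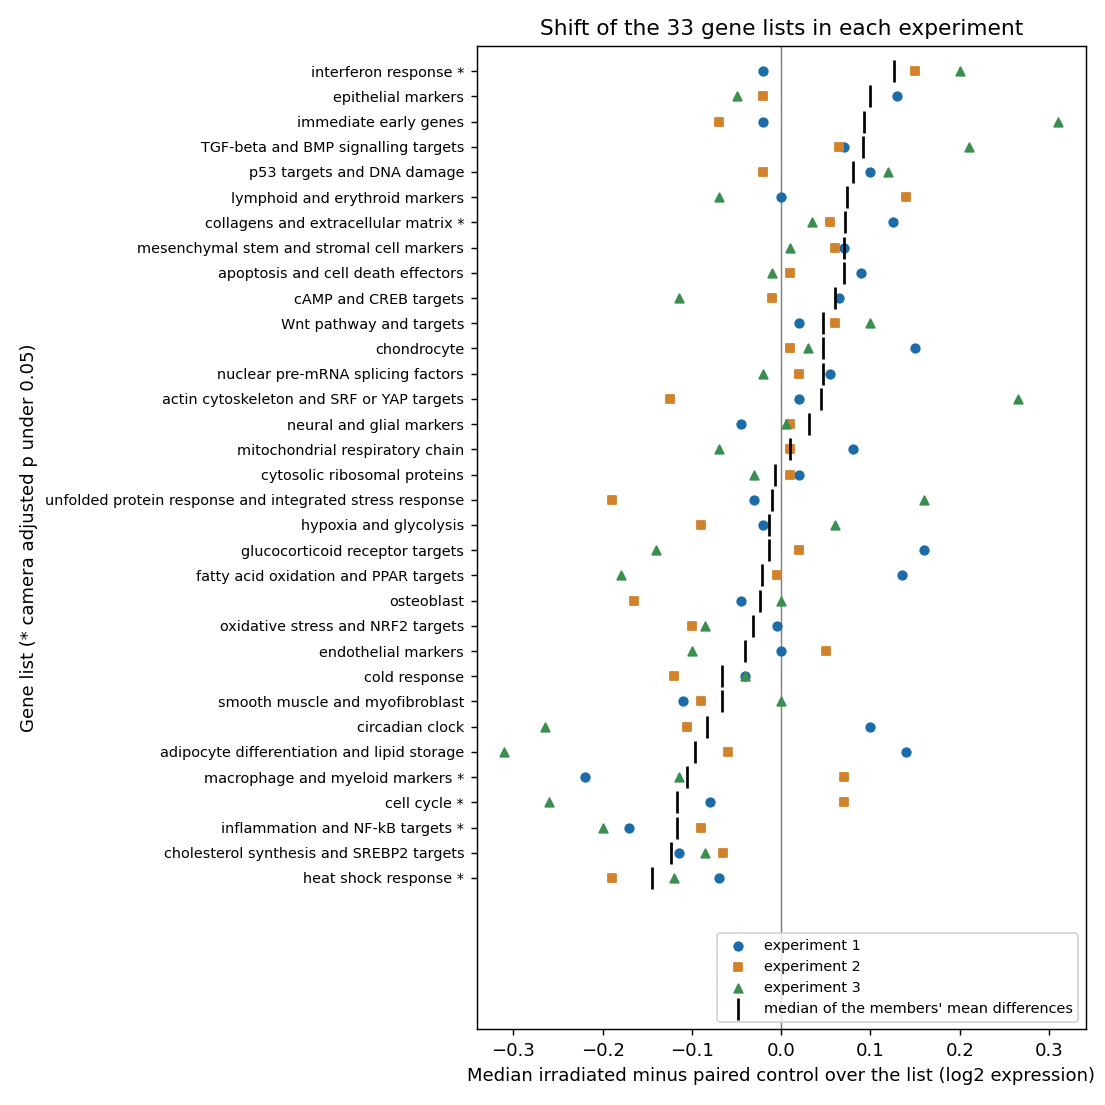
Median log2 difference, irradiated minus paired control, over the measured members (horizontal axis) of each of the 33 gene lists (vertical axis), with points for single experiments, a bar for the median of the members' mean differences and a star for a camera adjusted p under 0.05. The heat shock medians lie below 0 in all 3 experiments and the fat cell medians run from 0.14 to -0.31.

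The 3 experiments differed in how far their responses matched. Across the 9302 expressed genes 3470 (37.3%) had differences of 1 sign in all 3 experiments, where chance gives 25%, with 1726 higher and 1744 lower. The Pearson correlation of log2 differences across genes, which are not independent replicates, was 0.519 between experiments 1 and 2, 0.307 between 1 and 3, and 0.0658 between 2 and 3. Differences were widest in experiment 3, with an SD across genes of 0.318 against 0.205 and 0.227. RNA quality, read as the 3 prime minus 5 prime log2 signal of the Gapdh and beta-actin control probe sets, differed between the groups by -0.0067 ± 0.0176 (SD, n = 3), with a two-sided exact sign-flip permutation p of 0.75, where 0.25 is the smallest that 3 pairs allow.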

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

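The hybridisation controls, spiked-in transcripts added to each sample before hybridisation and used in no comparison, were brighter on the irradiated array of experiment 3 than on its control array, by 0.482 on the log2 scale. The mean signals were 11.99 and 11.51. In experiments 1 and 2 the same difference was 0.06 and 0.03, so this array stands apart from the other 2 irradiated arrays.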

How the results depend on the processing

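The alternatives that drop members from the heat shock or interferon list, or join an estimated correlation to an omission, were chosen after seeing the data. With the experiment as a random replicate block, probe sets and genes past the threshold rose from 0 to 2. Without moderation 15 probe sets passed, all with equal differences in the 3 experiments, which leaves no residual spread. Without the replicate block 0 passed, with 2168 at an unadjusted p under 0.05 where chance gives 2252, and the block changed no gene call. With experiments left out in turn the count of probe sets and of genes was 0 to 0, genes at least 1.5-fold different numbered 83 to 141, and gene lists past the threshold 3 to 9. The 1.5-fold genes numbered 141 without experiment 2. Lists past the threshold numbered 2 without the replicate block (heat shock and interferon), 3 with the random replicate block and 3 without experiment 1. They numbered 0 with fry and with an estimated correlation, alone or joined to each experiment or the dim probe sets left out. With an estimated correlation the 0 was close to fixed in advance by the few degrees of freedom. Those settings count among the alternatives below. Genes of 1 sign in all 3 experiments numbered 2123 (38.6%) at a mean of at least 8 and 5605 (30.8%) without a filter, where fewer or more genes were counted. The RNA quality difference was 0.0133 for Gapdh alone and -0.0267 for beta-actin alone. For the other shifts the cause was not tested. The heat shock call held under 11 of 18 alternatives and the interferon call under 12 of 20, with adjusted p up to 0.924; NF-kB and matrix lists held under 8 of 17 and myeloid under 7 of 17. Over the alternatives the 24 leading genes took 0.552 to 1.27 times their main value, with 1 of 264 values past the threshold; their direction was fixed in large part by the rule that chose them. Leaving out probe sets near background ended the NF-kB call (adjusted p = 0.153) and the cell cycle call (adjusted p = 0.21) and kept the heat shock (0.014), myeloid and interferon (0.0209 each) and matrix (0.0258) calls.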

Other observations

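Myeloid transcripts were read in all cultures. Lyz2, the macrophage lysozyme, had a mean log2 value of 14.18 over the 6 arrays, Csf1r, the receptor for macrophage colony-stimulating factor, 12.98, Tyrobp 12.72, C1qa 12.18 and Adgre1 10.22. Signals of different probe sets are not on 1 scale, so these values give no share of any cell type, and the source of the transcripts was not tested. The myeloid list median was 11.275 on the irradiated and 11.605 on the control array of experiment 1. In experiment 2 these medians were 12.21 and 12.235, and in experiment 3 they were 12.28 and 12.49. Which cells carried the NF-kB and matrix differences was not tested either.

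Genes outside the rule for named genes, chosen after their values were seen, had wide differences too. Slco4a1, an organic anion transporter, had a log2 difference of -1.96 ± 0.32 (SE) and Arg2, the mitochondrial arginase, of -1.73 ± 0.31 (SE). Several genes known as targets or feedback regulators of growth factor signalling were lower in all 3 experiments, Spry4 by -0.69, Epha2 by -0.68, Ereg by -0.64 and Phlda1 by -0.42. None passed the adjusted threshold. A list of 15 ERK feedback genes, the last of the 3 picked after the values were seen, had a median of 0.02 (fry adjusted p = 0.0671). Its medians in the 3 experiments were -0.01, -0.07 and -0.09, with 6 members lower and 1 higher in all 3, so its direction is not clear.

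All tests of explanations in the next 2 paragraphs were chosen after the results were seen, and the 3 gene lists tested with fry were picked then and adjusted together. The fall of the heat shock list may reflect lower osmolarity of the irradiated medium, since Hspa4l is also induced by hypertonic stress and the betaine transporter Slc6a12 differed by -1.39 at a dim level. The osmolyte transporters Slc38a2, Slc5a3 and Slc6a6, which had not raised the question, were lower in all 3 experiments with a median of -0.32. Their fry p was under 0.05 before adjustment over the 3 lists and not after it (fry adjusted p = 0.0671). Slc5a3, at -0.32, became -0.115 without experiment 3, and Slc6a6, at -0.26, became -0.16 without experiment 1. A cooler irradiated culture stays open too, since 18 other chaperones had a median of -0.09 (fry adjusted p = 0.0671). Of the 5 measured cold response genes, Cirbp and Srsf5 were higher in all 3 experiments, by 0.38 and 0.30. The other 3 were lower in all 3, and the list did not pass (camera adjusted p = 0.799). The brighter array of experiment 3 is argued against only as the sole source of the fall. Without that experiment the heat shock list still fell, with a median of -0.14 (camera adjusted p = 0.00714, or adjusted p = 0.907 with an estimated correlation). Whether that array bears on the size of the fall was not tested. Hspa1a differed by -2.38 in experiment 3, against -1.30 and -0.74 in experiments 1 and 2. An effect of the radiation itself was not tested apart from these.

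The rise of the interferon list may be noise near background or rest on a pair of neighbouring genes. Against the pair, the list without Tap1 and Psmb9 still rose (camera adjusted p = 0.0236, or adjusted p = 0.851 with an estimated correlation). Against background, the call held with dim probe sets left out (camera adjusted p = 0.0209, or adjusted p = 0.813 with an estimated correlation) and for the 10 expressed members, whose median was 0.11 (camera adjusted p = 0.02, or adjusted p = 0.851 with an estimated correlation). Both sets hold Tap1 and Psmb9, and the 8 other members with a mean of at least 6 over the 6 arrays had a median of 0.09 and did not pass (camera adjusted p = 0.264), so background stays open for the rest of the list. The loss of the call without experiment 3 and with fry (fry adjusted p = 0.257) leaves the rise itself open. The irradiated array of that experiment had the brighter hybridisation controls, and whether this bears on the rise was not tested. The loss with an estimated correlation cannot decide it, since that correlation was 0.000435, below the fixed 0.01, and the test had 2 degrees of freedom.

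The comparison with other splits was planned. The 6 arrays make 10 splits of 3 against 3, which are too few for a share under 0.05. Probe sets and genes past the threshold numbered 0 in all 10, and 0 is also the highest of the other splits. The 1.5-fold genes numbered 68 in the real split and up to 577 in the others, with 5 of 10 splits as large. The lists numbered 6 in the real split and up to 7, with 6 of 10 as large. A split that parts 1 pair rests, under the block, on the irradiated minus control difference of that experiment alone. Such splits gave 577 and 564 of these genes for experiment 3, 109 and 109 for experiment 2, and 30 and 29 for experiment 1. They are not groupings free of treatment, so the shares of 10 above do not weigh the real split. The 4 splits that part all 3 pairs are fewer still. Among the 4 splits that part all 3 pairs, the 1.5-fold genes numbered 68 in the real split and 33, 19 and 4 in the others, and the lists 6 in the real split and 4, 7 and 3 in the others. For the heat shock list the smallest camera adjusted p in these others was 0.0593, against 0.0014 in the real split. The interferon list passed in 1 of these others (camera adjusted p = 0.0387), against 0.0014 in the real split. Cell cycle and myeloid lists had smaller adjusted p in another of these splits, 3.06e-05 and 0.000161, than in the real one.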
